A study of Homo sapiens with 2 samples.

How the data were processed

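RNA was sequenced from 2 cultures of SKHEP1 cells, 1 with forced expression of human PPARG from a lentivirus and 1 with the empty vector, after 12 days of culture. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina. That kit as named does not mark strand, so reads of overlapping genes on opposite strands could not be told apart, and named genes whose spans overlap a neighbour are given as such in the results. Groups were taken from the labels, with 1 library in each.

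The authors deposited 1 table of FPKM values for 61802 genes, with gene names, Ensembl gene IDs, coordinates, gene types and other columns such as gene length in bases, which the authors used as the divisor. Per the submitters' processing notes, CASAVA, HISAT2, featureCounts 1.5.0-p3 and genome build GRCh38 were used. The roles and settings of these tools, the annotation release and the strand setting are not given in the sources used here. The 2 libraries' columns were matched to samples by the library names in the labels, and 0 columns of other samples were present.

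In each library, FPKM multiplied by gene length was a whole multiple of 1 step for 100% of values above 0, within 0.001 of a count. The counts per gene and the total that the authors divided by were therefore rebuilt. The sources used here do not say whether a count is a read or a read pair. The rebuilt counts summed to 18108956 in the control library and 16030030 in the PPARG library, or 91.3% and 95.9% of the totals used for FPKM (19844232 and 16715329). 22248 and 23314 genes had at least 1 count, and 11335 and 11523 had at least 1 FPKM. In a gene of 1 kb, 1 FPKM corresponded to 19.8 counts in the control library and 16.7 in the PPARG library, and the limit that a count of 0 allows (3 counts) to 0.151 and 0.179 FPKM.

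The deposited FPKM values were compared as log2((FPKM PPARG + 1)/(FPKM control + 1)), without rescaling between the libraries. This log2 scale, computed from the deposited values, understates the change of low genes. A gene was measured when it had at least 1 FPKM in at least 1 library, and was called higher or lower when its log2 ratio was at least 1 in size. With 1 library per group there are no residual degrees of freedom, so no test, p-value or standard error was computed. Fold values are ratios of FPKM without the added 1, with 95% exact conditional (Clopper-Pearson) intervals from the counts. FPKM values have 95% exact Poisson intervals. Both cover counting error only, since PCR copies are not independent molecules and nothing measures the spread between cultures. Where 1 library had 0 counts, the fold was computed against 3 counts in that library. Such a fold leaves out the counting error of the other library.

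The rule for the genes to name was fixed before the data were examined, as were the rule of size, the 32 gene lists and most alternatives. It takes PPARG, the 12 protein-coding genes with the largest rise and the 12 with the largest fall among those with at least 5 FPKM in 1 library, up to 4 measured members of each list with the largest log2 ratio in size, and ADIPOQ, FABP4, PLIN1, CEBPA, CD36, LPL and PLIN2. Other named genes were chosen after their values were seen: ALB, APOA1, LEP, CIDEA, UCP1, KDR, KRT8, KRT18, KRT19, COL6A3, COL1A1, COL1A2, DCN, FN1, ISG15, IFI6, IFIT2, IFIT3, DDX58, XAF1, IL6, IL11, CSF3, HES1, CHAC1, DNAJB9, HSP90B1, LYZ, MKI67, EIF3C, overlapping neighbours, and every gene of the lists added in the closing section. Values of some genes that the rule takes are not reported here.

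The 32 fixed lists cover adipocyte identity, PPAR target genes outside fat, thermogenic fat, preadipocyte and anti-adipogenic genes, PPAR and RXR partners, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, nuclear oxidative phosphorylation genes, the mitochondrial genome, extracellular matrix, mesenchymal transition, contractile and YAP or SRF targets, mitosis, DNA replication, p53 targets, CDK inhibitors, inflammatory cytokines and NF-kappaB targets, interferon response, unfolded protein and integrated stress response, hypoxia and glycolysis, NRF2 and antioxidant genes, lysosome and autophagy, cytosolic ribosome, reference genes, and markers of hepatocytes, endothelium, epithelium, bone and cartilage, macrophages, muscle and neurons. Of 639 list members, added lists included, 637 were found by gene name and 2 by gene ID under an older name. Some genes are in more than 1 list. A list with at least 3 measured members was described by the median of their log2 ratios and its place among 10000 random lists of the same size, matched on mean expression in 20 bins. The random range runs from the 2.5 to the 97.5 percentile of those medians. It is a description of these 2 libraries, not a p-value.

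The calculations were tested on simulated data. With counting noise alone, 43 of 11848 genes passed the 2-fold rule as higher and 38 as lower, and 5% of random lists lay outside the random range. Of 200 genes changed by 4-fold, 100% passed the rule. Of 200 genes changed by exactly 2-fold, 15.5% passed, since the added 1 shrinks the ratio (median size 0.93).

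The alternatives were pseudocounts of 0.1 and 0.5 FPKM, median centring, a trimmed mean scaling, rescaling to TPM with and without mitochondrial genes, other filters on low values, protein-coding genes only, 1.5-fold and 4-fold rules, leaving out genes under 500 bases, and a counting interval that excludes no change. Rescaling to the counts listed in the table, a correction for gene length in 20 bins, and random lists also matched on gene length were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.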

Results

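Gene expression was measured by RNA sequencing in SKHEP1 cells, a human line that the labels describe as derived from hepatocellular carcinoma. 1 culture had received a lentivirus that drives human PPARG, the nuclear receptor that directs fat cell differentiation and lipid storage. The control culture had received the empty lentiviral vector. Both were grown for 12 days in serum-containing medium before RNA was collected. The submitters describe the PPARG cells as differentiated, and the comparison asks how their transcriptome differed from that of the control cells. Each group had 1 library, with 18108956 counts over genes in the control library and 16030030 in the PPARG library. With 1 library per group the differences have no replicate check, and no p-value is given. A gene was therefore called higher or lower by a fixed rule of size, a 2-fold difference in FPKM + 1. Fold values are given without the added 1, with 95% intervals in parentheses that cover counting error only.

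PPARG itself differed between the libraries in the direction of the labels. PPARG (ENSG00000132170, chromosome 3, 12287368 to 12434356, plus strand, GRCh38) had 0.665 FPKM in the control library and 129 FPKM in the PPARG library, or 158 and 25849 counts. This was 194-fold (166 to 229) and a log2 ratio of 6.29 on the FPKM + 1 scale. Counts from the introduced and the endogenous PPARG gene were not separated in the table.

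Among 12321 measured genes, those with at least 1 FPKM in at least 1 library, 789 (6.40%) were at least 2-fold higher in the PPARG library and 443 (3.60%) were at least 2-fold lower. Of the genes past the rule, 64.0% were higher. The median log2 ratio of all measured genes was −0.0026 and the interquartile range was 0.675. Of 10386 protein-coding genes, 554 were higher and 237 were lower. Long noncoding RNA genes went the other way in number, with 55 higher and 90 lower of 883. Genes of other types made up the rest of both numbers. With genes under 500 bases left out, 613 were higher and 329 were lower. Transcripts of the mitochondrial genome held 4.74% of the counts in the control library and 4.79% in the PPARG library.

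**Figure D1:**
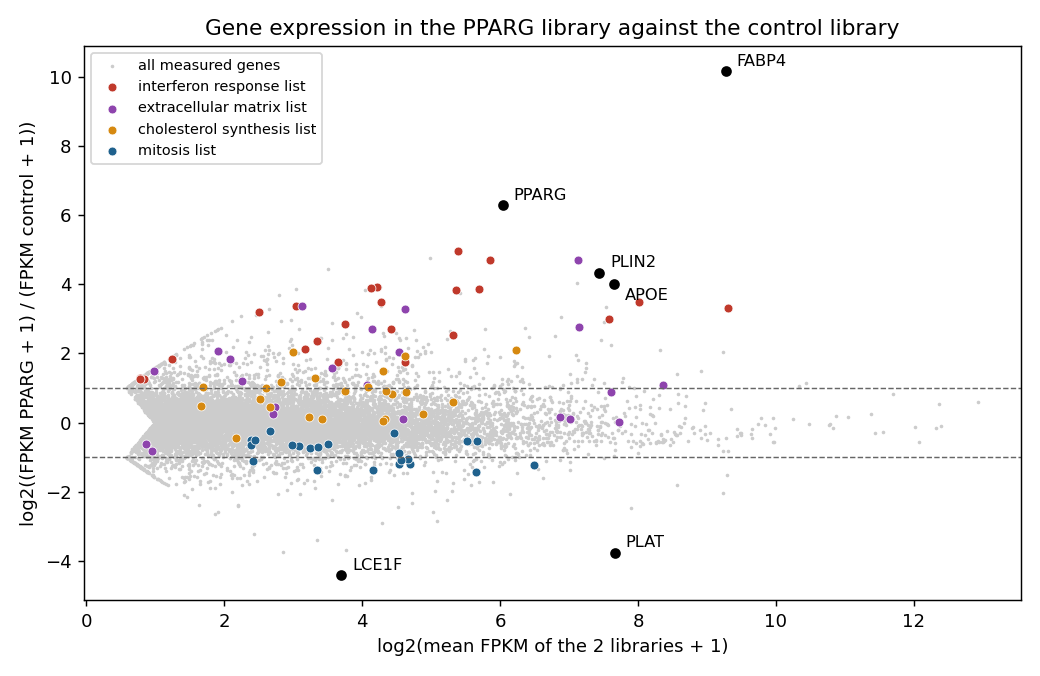
Log2 ratio of FPKM + 1 (PPARG over control) against log2 of the mean FPKM + 1 for the 12321 measured genes, 1 library per group. Coloured points are members of 4 gene lists, black points are named genes, and the dashed lines mark a 2-fold difference. All 23 interferon response genes lie above the upper line and the 22 mitosis genes lie below 0.

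The gene with the largest log2 ratio was FABP4 (ENSG00000170323, chromosome 8, 81478419 to 81483236, minus strand), which encodes a fatty acid carrier of fat cells and is a direct PPARG target. It had 2 counts in the control library and 28250 in the PPARG library, 1235 FPKM in the latter, a ratio of 16769 (4642 to 138474). PLIN2 (chromosome 9, 19108375 to 19149290, minus strand), a coat protein of lipid droplets, was 21.5-fold higher (20.4 to 22.6) and reached 330 FPKM. APOE, an apolipoprotein, was 16.8-fold higher (15.7 to 18.0). Of the other genes with the largest rises, 3 are in the interferon response list: OASL was 49.3-fold higher (42.9 to 56.9), IFIT1 33.3-fold (29.7 to 37.5) and IFI27 26.3-fold (21.7 to 32.3). The chemokine genes CCL20 and CCL5 were 48.5-fold (35.3 to 68.4) and 17.6-fold (15.9 to 19.4) higher. COL6A1 (chromosome 21, 45981770 to 46005050, plus strand), a collagen VI chain, was 28.4-fold higher (26.7 to 30.3). VTN, which encodes vitronectin, was 25.7-fold higher (19.4 to 34.8), although its span overlaps SARM1 on the other strand. S100P, a calcium-binding protein gene, had 0 counts in the control library and 163 in the PPARG library. Against the limit of 3 counts that a count of 0 allows, S100P was 64.5-fold higher, which leaves out the counting error of the 163 counts.

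The abundant gene with the largest difference in the other direction was PLAT (chromosome 8, 42174718 to 42207709, minus strand), which encodes tissue plasminogen activator. PLAT went from 377 FPKM in the control library to 26.8 FPKM in the PPARG library and was 14.1-fold lower (13.6 to 14.6). Several of the largest falls were of genes with few counts left in the PPARG library. LCE1F, a cornified envelope gene, had 343 and 2 counts (144-fold lower, 39.7 to 1198). KPRP, also of the cornified envelope, had 437 and 2 counts (184-fold lower, 50.6 to 1525). SMCP had 83 and 1 counts, a 69.9-fold difference (12.2 to 2794). The hair keratin-associated genes KRTAP2-3 and KRTAP2-4 are near-identical copies that can share reads, and their summed counts were 5.63-fold lower (5.29 to 6.0). IL24, a cytokine gene, was 24.9-fold lower (17.5 to 36.7), and its overlapping neighbour FCMR went from 2.24 to 0.455 FPKM. CMKLR2, a receptor gene, was 14.4-fold lower (9.39 to 23.3), HLA-DRA, an antigen-presentation gene, 7.97-fold (6.74 to 9.49), and the transcription factor KLF2 6.64-fold (5.97 to 7.39). TRIB3, a stress-induced pseudokinase gene, was 4.34-fold lower (4.10 to 4.60). EIF3CL was 23.0-fold lower (16.7 to 32.6), but its near-identical copy EIF3C went from 4.03 to 7.88 FPKM. The summed counts of EIF3CL and EIF3C were 1.43-fold lower (1.32 to 1.56), so the value for EIF3CL alone is uncertain.

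**Figure D2:**
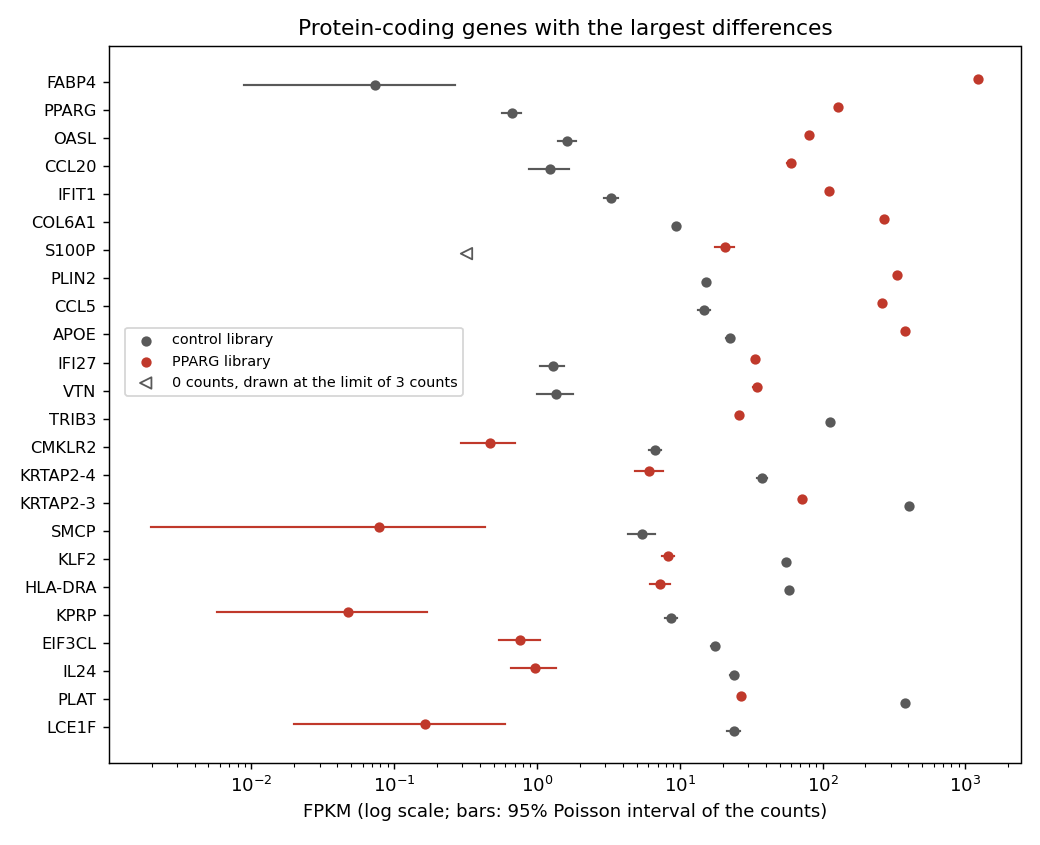
FPKM (log axis) of the 12 protein-coding genes with the largest rise and the 12 with the largest fall, in the control library (grey) and the PPARG library (red), ordered by log2 ratio of FPKM + 1. Bars are 95% Poisson intervals of the counts, and the open triangle marks S100P, which had 0 control counts, at the limit of 3 counts. FABP4 went from 0.0736 to 1235 FPKM and PLAT from 377 to 26.8 FPKM.

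Some adipocyte identity genes were higher, and others had counts near 0 in both libraries. Of 28 adipocyte identity genes, 10 were measured, 4 were higher and none was lower. Besides FABP4, these were the lipid droplet genes PLIN4, with 8 and 1560 counts (232-fold higher, 117 to 537), and CIDEC, with 4 and 58 counts (17.2-fold, 6.37 to 65.3), and the lipase gene LIPE (5.90-fold, 4.47 to 7.90). PLIN4 overlaps HDGFL2 on the other strand. The list's median log2 ratio was 0.82, and 1 of 10000 random lists of the same size and expression had a median as high. All 4 higher genes were under 1 FPKM in the control library and passed the filter through the PPARG library. With no filter on low values the median was 0.52 over 21 genes, also above its random range. Of the 10 measured genes, 1 lay below 0. That gene, ACSL1, went from 2.88 to 1.53 FPKM and did not pass the rule. ADIPOQ, LEP and CIDEA, which encode the hormones adiponectin and leptin and a lipid droplet protein, had 0 counts in both libraries. With 0 counts, the limit for ADIPOQ was 0.0390 FPKM in the PPARG library. PLIN1 had 1 and 5 counts, CD36 had 1 and 38, and LPL had 0 and 1, all under 1 FPKM. CEBPA, the transcription factor that acts with PPARG in fat cell differentiation, had 28 counts in the control library and 8 in the PPARG library.

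The list of PPAR target genes outside fat lay above its random range. Of 20, 15 were measured, 8 were higher and none was lower, with a median of 1.02 and 0 of 10000 random lists as high. Besides PLIN2, these included HILPDA, an inhibitor of lipolysis (4.90-fold, 4.39 to 5.48), ANGPTL4, an inhibitor of lipoprotein lipase (3.94-fold, 3.77 to 4.11), and FABP5, another fatty acid carrier (3.16-fold, 2.96 to 3.37). Of the 15, 13 lay above 0 and 2 below, neither past the rule. TXNIP went from 319 to 210 FPKM and MGLL from 14.8 to 9.56 FPKM. The median of 1.02 was the value of PDK4, which went from 0.0222 to 1.07 FPKM and passed the filter through the PPARG library. With no filter on low values it was 0.88 over 18 genes, also above its random range. Among 17 measured PPAR and RXR partners of 22, the median of 0.12 was inside the random range. For genes with 5 FPKM or more the median was −0.22, also inside. Of the 17, 3 were higher and none was lower. The 3 were NR1H3, which encodes the sterol-sensing receptor LXR alpha (7.45-fold, 6.41 to 8.69), CEBPD (4.55-fold, 4.11 to 5.04) and the coactivator NCOA3 (3.59-fold, 3.31 to 3.90). NR1H3 overlaps ACP2 on the other strand. PPARD, a related receptor gene, was 1.91-fold lower (1.76 to 2.07) and did not pass the rule.

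Preadipocyte and anti-adipogenic genes went in both directions. Of 16, 11 were measured, 2 were higher and 3 were lower, and the median of 0.0075 was inside the random range. The surface marker THY1 was 3.89-fold higher (3.63 to 4.16) and the growth factor receptor gene PDGFRB 5.77-fold higher (4.76 to 7.06), whereas KLF2, SOX9 and HES1 were lower, SOX9 by 3.40-fold (3.17 to 3.65) and HES1 with a log2 ratio of −1.04. Of 14 thermogenic fat genes only DIO2 was measured, a thyroid hormone deiodinase gene with 25 and 1280 counts (60.8-fold higher, 41.0 to 94.3). UCP1, the thermogenic uncoupling protein gene, had 0 counts in both libraries.

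The median of each lipid synthesis list was above its random range, although most members did not pass the rule. Of 23 measured cholesterol synthesis genes of 24, 8 were higher, none was lower and 22 lay above 0, with a median of 0.88 and 0 of 10000 random lists as high. HMGCS1, which makes the HMG-CoA precursor, was 5.59-fold higher (4.91 to 6.39) and MSMO1 4.06-fold (3.68 to 4.48). Of 19 measured fatty acid and triglyceride synthesis genes of 22, 5 were higher and none was lower, with a median of 0.59 and 1 of 10000 random lists as high. SCD, which desaturates fatty acids, was 4.33-fold higher (4.25 to 4.42) and reached 518 FPKM. FADS2, another desaturase gene, was 2.80-fold higher (2.58 to 3.05), LPIN1 2.63-fold (2.42 to 2.86) and ACSL3 2.37-fold (2.26 to 2.5). FADS2 overlaps FADS1 and FEN1.

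The fatty acid oxidation list also had a median above its random range, and most of its members did not pass the rule. Of 19 measured genes of 22, 4 were higher and none was lower, with a median of 0.36 and 63 of 10000 random lists as high. They included EHHADH of the peroxisome (5.65-fold, 4.43 to 7.29) and ACADVL and SLC25A20 of mitochondria (2.60-fold, 2.5 to 2.70, and 2.82-fold, 2.40 to 3.32). ACADVL overlaps DLG4 on the other strand. The nuclear genes of oxidative phosphorylation, all 26 measured, and the 13 genes of the mitochondrial genome had no member past the rule, and their medians of −0.15 and −0.09 were inside the random range. Among them, NDUFB8 was 1.58-fold lower (1.32 to 1.89) and MT-CO2 1.49-fold lower (1.47 to 1.51).

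The interferon response list had the largest median of the 27 fixed lists with at least 3 measured members. All 23 measured genes of 24 were higher, with log2 ratios from 1.25 (XAF1) to 4.95 (OASL), a median of 3.0 and 0 of 10000 random lists as high. The added 1 shrinks the ratio of XAF1, which went from 0.0152 to 1.42 FPKM, so this range does not rank the genes by fold. Some of the 23 measured genes, XAF1 among them, were under 1 FPKM in the control library and passed the filter through the PPARG library. With no filter on low values the median was 2.93 over 24 genes, also above its random range. OAS1, which senses double-stranded RNA, was 26.5-fold higher (23.7 to 29.8). ISG15 and IFI6, chosen after their values were seen, reached 475 and 1143 FPKM. DDX58, the unmeasured member, had 7 and 37 counts. IFIT1, IFIT2 and IFIT3 have spans overlapping LIPA on the other strand.

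Inflammatory cytokine and NF-kappaB target genes were split. Of 24, 18 were measured, 5 were higher and 2 were lower, and the median of 0.21 was inside the random range. It was above the range when only genes with 5 FPKM or more were kept (0.93), when the mean FPKM had to reach 1 (0.61) and with a correction for gene length (0.33). Besides CCL20 and CCL5, the apoptosis inhibitor gene BIRC3 was 4.98-fold higher (4.39 to 5.65), the adhesion molecule gene ICAM1 3.61-fold higher (3.40 to 3.84) and IL6, chosen after its value was seen, 2.44-fold higher (2.28 to 2.60). The 2 lower genes were IL11 and CSF3, with log2 ratios of −1.26 and −1.25 that the added 1 shrinks. IL11 went from 1.66 to 0.112 FPKM and CSF3 from 1.63 to 0.108 FPKM.

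Extracellular matrix genes had a median above their random range. Of 24, 22 were measured, 13 were higher and none was lower, with a median of 1.14 and 0 of 10000 random lists as high. Besides COL6A1, the laminin gene LAMA4 was 27.9-fold higher (23.4 to 33.6), the collagen gene COL3A1 12.1-fold (11 to 13.4) and COL6A2, which lies beside COL6A1 on chromosome 21, 6.91-fold (6.67 to 7.15). Some of the higher genes, LAMA4 among them, were under 1 FPKM in the control library and passed the filter through the PPARG library. With no filter on low values the median was 1.08 over 24 genes, also above its random range. Members chosen after their values were seen show the exceptions. COL6A3, another collagen VI chain gene, went from 1.46 to 0.392 FPKM, a log2 ratio of −0.82 that did not pass the rule. COL1A1 was 2.80-fold lower (2.11 to 3.75), with a log2 ratio of −0.63 that did not pass the rule. COL1A2 had 0 and 1 counts, DCN had 1 and 4 counts, and FN1, encoding fibronectin, was 1.13-fold higher (1.11 to 1.15) without passing the rule.

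The mitosis and DNA replication lists had medians below their random ranges, and most of their members did not pass the rule. All 22 measured mitosis genes of 24 lay below 0 and 9 passed the rule, with a median of −0.72 and 0 of 10000 random lists as low. CCNB2, a cyclin gene, was 2.91-fold lower (2.5 to 3.41), the ubiquitin-conjugating enzyme gene UBE2C 2.76-fold (2.51 to 3.04), the kinase gene PLK1 2.75-fold (2.53 to 3.0) and CDC20 2.37-fold (2.25 to 2.5). Of 23 measured DNA replication genes of 25, 22 lay below 0, 7 were lower and none was higher, with a median of −0.70 and 0 of 10000 random lists as low. The replication licensing gene CDC6 was 2.98-fold lower (2.57 to 3.45), CDC45 2.70-fold (2.25 to 3.26) and the helicase gene MCM7 2.5-fold (2.38 to 2.63). MCM7 overlaps AP4M1 on the other strand. MKI67, chosen after its value was seen, was 1.73-fold lower (1.62 to 1.84). Transcripts remained at 6.80 FPKM for MKI67 and 52.9 FPKM for CDC20 in the PPARG library.

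The CDK inhibitor list, with 5 of 7 genes measured, had no member past the rule and a median of −0.14, inside the random range. CDKN1A, which encodes p21, went from 302 to 259 FPKM. Of 20 measured p53 target genes of 22, none passed the rule and 17 lay below 0. Their median of −0.39 was below the random range, with 28 of 10000 random lists as low, and GDF15 was 1.78-fold lower (1.74 to 1.81). All 24 cytosolic ribosome genes were measured and lay below 0, and none passed the rule. Their median was −0.41, with 37 of 10000 random lists as low, and RPL3 was 1.57-fold lower (1.54 to 1.59).

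Stress response genes went in both directions. Of 21 measured unfolded protein and integrated stress response genes of 22, 2 were higher and 5 were lower, and the median of 0.17 was inside the random range. It was above the range for genes with 5 FPKM or more (0.27) and with a correction for gene length (0.30). Besides TRIB3, the lower genes included SESN2 (3.48-fold, 3.25 to 3.73), PPP1R15A (2.78-fold, 2.64 to 2.92) and the serine synthesis gene PHGDH (2.51-fold, 2.36 to 2.68). CHAC1 was the fifth, with a log2 ratio of −1.12. The 2 higher genes were DNAJB9 and HSP90B1, which encode chaperones of the endoplasmic reticulum, with log2 ratios of 1.22 and 1.04. Of 17 measured NRF2 and antioxidant genes of 22, 3 were higher and none was lower, and the median of 0.27 was inside the random range. It was above the range with no filter on low values (0.35), for genes with 5 FPKM or more (0.39) and, unchanged in value, with random lists also matched on gene length. The 3 were CAT, which encodes catalase (6.65-fold, 5.93 to 7.46), SOD2 (4.90-fold, 4.71 to 5.10) and HMOX1 (3.90-fold, 3.70 to 4.10). GPX1 was 1.75-fold lower (1.67 to 1.83) and did not pass the rule. SOD2 overlaps ACAT2 and WTAP on the other strand.

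Hypoxia and glycolysis genes had 20 of 22 members measured, 5 higher and none lower, with a median of 0.42 and 19 of 10000 random lists as high. Among genes with 5 FPKM or more the median was 0.25, inside the range. The peptide hormone gene ADM was 4.77-fold higher (4.58 to 4.96) and NDRG1 3.34-fold higher (3.13 to 3.57). All 23 lysosome and autophagy genes were measured, 3 were higher and none was lower, with a median of 0.38 and 7 of 10000 random lists as high. LIPA, the lysosomal acid lipase gene, was 3.36-fold higher (3.27 to 3.46) but overlaps the IFIT genes. GABARAPL1 was 2.32-fold higher (2.23 to 2.42) and the protease gene CTSD 2.26-fold higher (2.16 to 2.37).

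**Figure D3:**
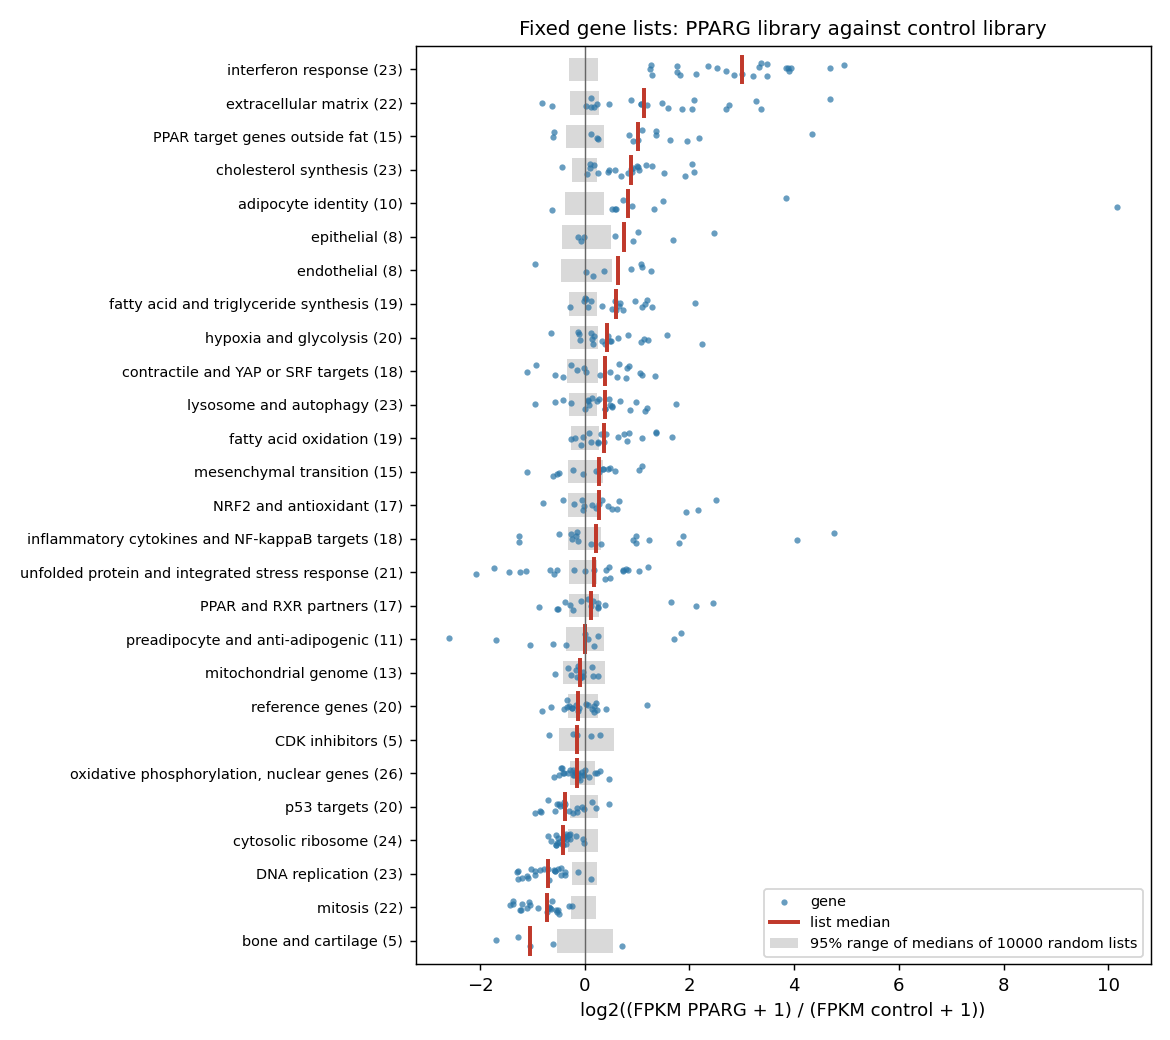
Log2 ratio of FPKM + 1 (PPARG over control, 1 library each) of the measured members of the 27 fixed lists with at least 3 measured members (points), with the list median (red line) and the range of medians of 10000 random lists (grey, 2.5 to 97.5 percentiles). The number of measured members is in parentheses. The interferon response median of 3.0 lies farthest above its range, and 12 lists lie above and 5 below theirs.

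Markers of other cell types were mostly below the level of a measured gene in both libraries, although some epithelial keratin genes were abundant. Of 24 hepatocyte genes only SERPINA1 was measured (3.98 and 4.59 FPKM), and the albumin gene ALB and APOA1 had 0 counts in both libraries. Of 24 endothelial genes 8 were measured, 3 were higher and none was lower, with a median of 0.63 and 103 of 10000 random lists as high. The 3 were ICAM2 (7.45-fold, 4.51 to 13), ESAM (7.03-fold, 3.88 to 13.8) and EGFL7 (2.21-fold, 2.01 to 2.44). ROBO4 was 2.42-fold lower (2.07 to 2.84), with a log2 ratio of −0.96 that did not pass the rule. ICAM2 overlaps PRR29 on the other strand. With no filter on low values the endothelial median was 0.08, inside the range, and KDR, a vascular growth factor receptor gene, had 0 counts in both libraries. Of 18 epithelial genes 8 were measured, 3 were higher and none was lower, with a median of 0.75 and 27 of 10000 random lists as high. Their median was inside the range with no filter (0.04) and for genes with 5 FPKM or more (0.57). The transcription factor gene ELF3 was 13-fold higher (10.4 to 16.4) and the keratin gene KRT7 3.53-fold higher (3.20 to 3.91). Other keratin genes were abundant in both libraries without passing the rule. KRT18 had 943 FPKM in the control library and 893 in the PPARG library, KRT19 466 and 424, and KRT8 402 and 598. KRT8 and KRT18 overlap each other on opposite strands.

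Among 18 measured contractile and YAP or SRF target genes of 22, 3 were higher and 1 was lower, with a median of 0.39 and 34 of 10000 random lists as high. With no filter on low values the median was 0.13, inside the range. LATS2 was 2.59-fold higher (2.47 to 2.71) and MYL9 2.17-fold higher (2.07 to 2.27), while the receptor kinase gene AXL was 2.15-fold lower (2.09 to 2.22). Of 15 measured mesenchymal transition genes of 20, 2 were higher (LOXL2 and S100A4) and 1 was lower (AXL), and the median of 0.27 was inside the range. LOXL2 was 2.15-fold higher (2.11 to 2.2). FOXC2 was 1.72-fold lower (1.39 to 2.14) and did not pass the rule. Of 15 bone and cartilage genes 5 were measured and 3 were lower, with a median of −1.05 and 3 of 10000 random lists as low. Besides SOX9, these were RUNX2, the transcription factor of bone formation (2.86-fold, 2.42 to 3.39), and SPP1 (2.77-fold, 2.5 to 3.06). MATN3 was 2.61-fold higher (1.78 to 3.90), with a log2 ratio of 0.70 that did not pass the rule. RUNX2 overlaps SUPT3H on the other strand, and with no filter the list's median was −0.09, inside the range.

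The macrophage, muscle and neuron lists each had 1 measured gene. CD14 had 1.62 and 1.60 FPKM, TNNT1 had 53.4 and 44.5 FPKM, and ENO2, also in the glycolysis list, was 2.18-fold higher (2.05 to 2.31). Of 20 reference genes 1 passed the rule, B2M, the light chain of HLA class I (2.29-fold higher, 2.23 to 2.35). The median of the reference genes was −0.12, inside the random range, and RPLP0 was 1.76-fold lower (1.73 to 1.78).

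Of the 27 lists with at least 3 measured members, 17 lay outside the random range. Lists of genes that are regulated together can leave that range with any difference between 2 cultures, so the number describes these 2 libraries. Log2 ratios had a weak trend with gene length across genes, with medians from −0.10 in the shortest of 5 equal groups to 0.08 in the longest (Spearman rho 0.106, genes not being independent replicates). More genes passed the rule in the shortest group, with 292 higher and 226 lower, than in the longest, with 107 and 29.

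Some further named genes have spans that overlap a neighbour, which makes their values less certain. On the other strand, IL6 overlaps STEAP1B and the noncoding gene IL6-AS1, and NDUFB8 overlaps HIF1AN. On the same strand, LOXL2 overlaps ENTPD4, S100A4 overlaps S100A3, KRT7 overlaps KRT86, ENO2 overlaps LRRC23 and PLIN1 overlaps PEX11A. S100A3 went from 11.4 to 34.9 FPKM, so the value of S100A4 is uncertain. AXL, GDF15, RPL3, ISG15 and IFI6 overlap noncoding or pseudogene entries of the table.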

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

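Rescaling to the listed counts, the correction for gene length and the matching on gene length were chosen after the data were seen; the other settings were planned. The numbers of genes past the rule moved by over 1.5 times with the pseudocount, filter and rule of size. A pseudocount of 0.1 FPKM gave 1222 genes higher and 867 lower, a filter of 5 FPKM gave 465 and 237, a 1.5-fold rule gave 1799 and 1492, and a 4-fold rule gave 134 and 27 (83.2% of them higher). Protein-coding genes alone gave 237 lower. The other settings kept both numbers within 1.5 times. Leaving out genes under 500 bases gave 613 higher and 329 lower. Requiring that the counting interval exclude no change gave 687 and 377. The PPARG log2 ratio was 7.40 with a pseudocount of 0.1 and 6.80 with 0.5, because its control level lies below 1 FPKM. No list median outside its random range changed sign, and 12 of the 17 such lists stayed on their side in all 12 settings tried on lists. The endothelial, contractile, epithelial and bone lists were inside the range with no filter, which adds genes near 0 counts, and the epithelial and hypoxia lists were inside it at 5 FPKM or more. The inflammatory, unfolded protein and NRF2 lists moved above the range in some settings, and the cause was not tested. The scalings moved the median of genes by at most 0.07 on the log2 scale. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. Depth limits genes near 0 counts: the intervals of LCE1F, KPRP, SMCP and FABP4 span more than an order of magnitude.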

Other observations

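The HLA, metallothionein, HOXB, immediate-early and interferon ligand lists, the choice of YAP target genes and the tests of explanations in this part were chosen after the results were seen, while the scalings those tests use were planned except rescaling to the listed counts. Antigen presentation genes that passed the rule were higher in class I and lower in class II. Ranks among random lists are not given for these lists, since they were picked for their values. Of 12 measured HLA class I pathway genes, 6 were higher in the PPARG library and none was lower, with a median log2 ratio of 0.97. HLA-C was 2.40-fold higher (2.32 to 2.48) and the peptide transporter gene TAP1 2.16-fold higher (2.06 to 2.27). Of 8 measured HLA class II pathway genes, 5 were lower and none was higher, with a median of −1.36. With no filter on low values the class II median was −0.63 over 13 genes. HLA-DRA went from 58.3 to 7.31 FPKM, and CD74, the invariant chain, was 4.13-fold lower (3.88 to 4.41). CIITA, the activator of class II genes and a member of this list, was 3.05-fold lower (2.64 to 3.54) but did not pass the rule on the FPKM + 1 scale. HLA-DMA lay above 0 and did not pass the rule, with 16.7 and 21.6 FPKM. TAP1 overlaps PSMB9 and HLA-DMA overlaps BRD2, each on the other strand. HLA-DRB1 and HLA-DRB5 are near-identical, and their summed counts were 3.58-fold lower (2.96 to 4.36).

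Some members of other groups were lower in the PPARG library. Of 4 measured metallothionein genes, which encode metal-binding proteins, 2 were lower, with a median of −1.26. MT2A went from 970 to 235 FPKM and MT1E was 3.63-fold lower (3.23 to 4.08). These genes are similar in sequence, and their summed counts were 4.07-fold lower (3.94 to 4.22). Of 8 measured HOXB cluster genes, 4 were lower, with a median of −0.93. HOXB9 was 3.37-fold lower (3.14 to 3.61) and HOXB5 3.83-fold lower (3.09 to 4.77), whereas HOXB13, at the end of the cluster, had 8.67 and 9.80 FPKM. Neighbouring HOXB genes overlap, so their values are not independent. Of 11 measured immediate-early genes, 4 were lower and 2 were higher, with a median of −0.67. EGR1 was 5.17-fold lower (4.22 to 6.37) and FOS had 121 and 9 counts, while KLF6 was 2.41-fold higher (2.33 to 2.48).

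The interferon response genes were higher by a median log2 ratio of 3.0. The 20 type I and III interferon ligand genes of the added list held 0 counts in the control library. They held 2 in the PPARG library, 1 each for IFNB1 and IFNW1. RNA was collected only after 12 days, so these counts cannot tell whether ligand genes were expressed earlier. They do not bear on whether an interferon raised the response genes. The scalings tried were too small to account for the higher interferon response genes. The largest shift was 0.0716. Taking it off moved XAF1, the lowest of the 23 measured genes on the FPKM + 1 scale, from 1.25 to 1.18. The macrophage list's summed FPKM was higher by 0.945, or 0.0393% of the 2406 FPKM by which the interferon list was higher, and LYZ had 0 counts. Both libraries are from a cultured line, so low macrophage values were likely beforehand. Little can be drawn from them on blood cells, and other blood cell types were not examined. A difference in vector load or culture cannot be told apart from an effect of PPARG, because there is 1 library per group.

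The mitosis and DNA replication lists had medians of −0.72 and −0.70, with 9 of 22 and 7 of 23 measured genes past the rule as lower. Gene length bias is argued against as the whole cause, since the medians after correction for gene length were −0.74 and −0.66. The scalings tried were too small to account for the mitosis difference, since the highest mitosis median over them was −0.71. A denser culture at collection stays open: 8 target genes of YAP, a regulator less active in dense cultures (CCN1, CCN2, ANKRD1, AMOTL2, AJUBA, LATS2, AXL and F3), had a median of −0.34 with 5 below 0 and 3 above, while the whole contractile and YAP or SRF list had 0.39. An effect of PPARG, the difference between the groups by design, stays open and was not tested.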
